A study of Homo sapiens with 6 samples.

How the data were processed

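RNA from A549 cells, a human lung adenocarcinoma line, was measured by poly(A)-selected, strand-specific RNA sequencing in 6 libraries. Per the labels, 2 libraries received a non-targeting control siRNA, 2 received TIMM13 siRNA 1 and 2 received TIMM13 siRNA 2. These groups were taken from the sample titles: the treatment field of all 6 samples names cell differentiation instead, and the control columns of the table are headed NC, so the meaning of the groups rests on the titles. The labels number the replicates 1 and 2 in each group and do not say whether these were separate cultures, so every p-value measures only the spread between these samples.

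The deposited values are a signal per gene, not counts: non-negative fractions in 1 table of 19990 gene symbols and 6 columns, scaled by the authors to the depth of each library and, from the look of the values, to transcript length. The submitters' processing notes name Trim Galore, STAR and featureCounts and the human build hg38, without versions, roles or order, and the tool that made these fractional values is not given in the sources used here. Whether the unit is FPKM or TPM is not stated, and the columns sum to between 205986 and 299936. Read counts were not recovered from these fractions. Depth is therefore unknown, and no counting interval or detection floor is given. A 0 in such a table need not mean that a gene is silent: all 13 mRNAs encoded by mitochondrial DNA, which every cell of this kind uses, are listed at 0 in all 6 libraries. The sources used here do not say why, and whether a 0 of a nuclear gene has the same origin is unknown. A gene is therefore only said to be listed at 0, with each library's value and no fold against such a group.

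The design fixed before the data were examined assumed counts and named a count test, with a fallback for a normalized unit. Because the table holds a normalized unit, the fallback was used, and the planned count tests and the filter on a mean count were not run. Genes with a value of at least 1 in at least 2 libraries were kept, which left 11486 of 19990. The values were used as log2(value + 1) with no further scaling. A linear model with 1 term per group was fitted over all 6 libraries, which leaves 3 residual degrees of freedom, and tested with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust options). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 11486 genes. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values, and are given with the standard error of the fit. Values per group are means ± SD of 2 libraries.

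The comparisons were siRNA 1 against control, siRNA 2 against control, the mean of both siRNAs against control, and siRNA 1 against siRNA 2. The fold changes and the overlap of the first 2 were set beside 100 simulations in which neither siRNA had an effect and both were compared with the same controls, and the overlap also beside that of independent lists. Each simulated gene had the same spread in all 6 libraries. Each of 24 gene lists fixed before the data were examined was tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested, which was so for 22 lists. Camera's adjusted p was taken over the 22 lists, and the test was repeated with a correlation estimated from the data, with fry and with cameraPR. The list tests of siRNA 1 against siRNA 2 were added after the data were seen. The other 2 lists were the mitochondrial-DNA mRNAs, with 0 members tested, and markers of leukocytes, fibroblasts and endothelium, with 3.

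Genes named in the text were chosen by a rule fixed before the data were examined, among genes with a mean of at least 1 and excluding clone-style names, long non-coding names and annotated pseudogenes. It takes TIMM13, the 12 largest rises and 12 largest falls among genes called the same way with both siRNAs (ranked by the smaller of their 2 changes), and from each list up to 4 members with the smallest p for the mean of both siRNAs. It also takes the 5 highest and 5 lowest called genes of siRNA 1 against siRNA 2, and up to 3 per direction of those called in opposite directions. Some genes that this rule takes are not used here. Any other gene named was chosen after its values were seen, and is said to be.

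Gene symbols were matched to GENCODE release 29 on GRCh38, the same assembly as hg38, for coordinates, transcript numbers and transcript lengths. Of the symbols, 19831 matched (99.2%). The table has 1 row per gene symbol, and the sources used here do not say how the transcripts of a gene were combined.

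The gene test was tested on simulated data made from the real genes' means and residual spread, with 200 genes of a mean of at least 5 changed in both siRNA groups in each of 20 simulations over 11486 genes. For siRNA 1 against control it called 1.42% of genes changed 2-fold, 42.8% of those changed 4-fold and 69.5% of those changed 16-fold, and 0.0337% of unchanged genes. For siRNA 2 against control the shares were 1.49%, 42.8%, 68.3% and 0.0341%. For the mean of both they were 11.6%, 50.7%, 74.3% and 0.0447%. In the simulated comparison of siRNA 1 with siRNA 2, where no gene differed, 0.000443% of unchanged genes were called. For the mean of both siRNAs, camera called 20 of 20 lists moved by 1 log2 unit and 0 other lists with the preset correlation, and 11 of 20 with an estimated one. Simulated genes varied independently of each other, with the same spread in all groups. In the data the estimated correlation was 0.278 for the G2/M list and 0.725 for cytosolic ribosomal proteins. The 0 other lists therefore do not measure how often camera wrongly calls lists whose genes move together.

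The alternatives were other pseudocounts, no filter and a filter at a value of 5, 3 other scalings (median of ratios, upper quartile, equal totals), a fit of only the groups compared (for the mean of both siRNAs, all 4 siRNA libraries as 1 group), the replicate number as a block, and leaving out each library in turn. Added after the data were seen were a run on genes with 1 annotated transcript (665 tested), library weights, and list tests on genes within 2-fold between replicates. For lists, upper-quartile scaling, equal totals and the pseudocounts were also added then. The library weights came out equal within each group (2.41 in control, 1.96 in siRNA 1 and 0.211 in siRNA 2), so they do not tell replicates apart. Bootstrap errors in the closing section come from 1000 resamples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.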

Results

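Gene expression was measured in A549 cells, a lung adenocarcinoma line, after transfection with a non-targeting control siRNA or with 1 of 2 siRNAs against TIMM13. TIMM13 encodes a small chaperone of the mitochondrial intermembrane space that escorts membrane proteins during import. The design text asks how TIMM13 acts on cell proliferation. Each group held 2 libraries. The deposited table gives depth-scaled abundances, so the read depth of the libraries is unknown. The column totals were 209245 and 209559 in the control libraries, 216524 and 219820 in the libraries labelled siRNA 1, and 205986 and 299936 in those labelled siRNA 2. The labels do not say whether replicates were separate cultures, so every p-value below measures only the spread between these samples.

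Replicates differed by a median SD of 0.0864 log2 units in the control group, 0.102 in siRNA 1 and 0.320 in siRNA 2. Of 11486 tested genes, 7.86% were over 2-fold apart between the control replicates, 7.09% between the siRNA 1 replicates and 19.5% between the siRNA 2 replicates. The library labelled siRNA 2 replicate 2 stood apart: across genes, which are not independent replicates, its log2 values correlated at 0.805 with siRNA 2 replicate 1 and at 0.745 to 0.772 with the libraries of the other groups. The other replicate pairs reached 0.888 and 0.895. Where a run below leaves out a library, its group keeps 1 library and the spread comes only from the other 2 groups, so such counts are given as a check of stability and not as results. The share of genes over 2-fold apart grew with the number of transcripts annotated for the gene. Among genes with a mean of at least 5 it was 2.47% between the control replicates for the 365 genes with 1 transcript and 12.9% for the 1211 genes with 16 or more. A change given below for a single gene with several transcripts could be one of transcript and not of level.

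**Figure D1:**
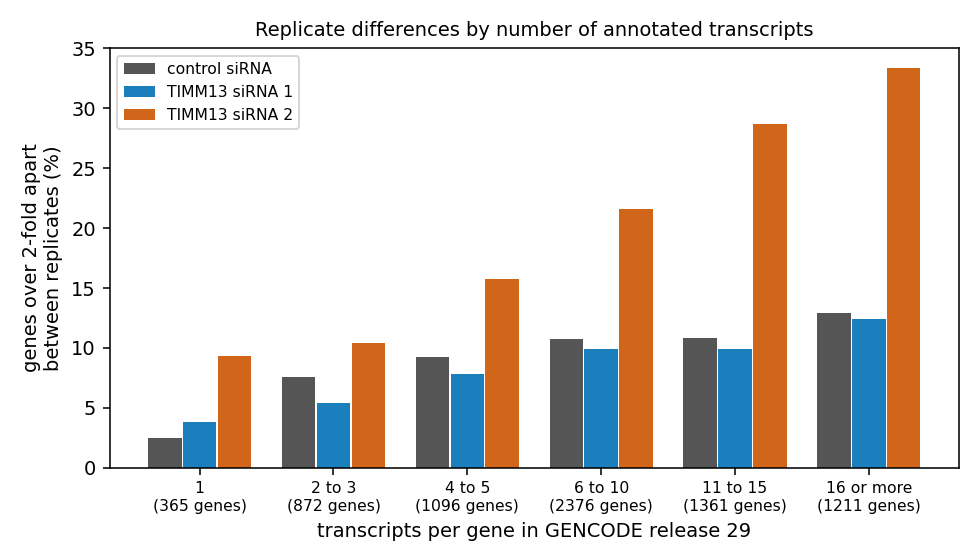
Bars give the percentage of genes over 2-fold apart between the 2 libraries of a group (y axis) for genes with a mean of at least 5, by number of transcripts in GENCODE release 29 (x axis). The share grows from 2.47% to 12.9% in the control group and from 9.32% to 33.4% in siRNA 2.

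TIMM13 itself was not detectably lower in the libraries of either siRNA. It stood at 2.09 and 2.56 in the control libraries, 2.09 and 1.83 in those labelled siRNA 1, and 1.82 and 2.31 in those labelled siRNA 2, or 2.32 ± 0.332, 1.96 ± 0.183 and 2.06 ± 0.344 (SD, n = 2). The log2 fold changes were −0.16 (SE 0.167, limma adjusted p = 0.653) for siRNA 1 and −0.12 (SE 0.167, adjusted p = 0.666) for siRNA 2. The gene (ENSG00000099800) lies on chromosome 19 at 2425624 to 2427894 of GRCh38, minus strand, with 3 exons in its longest transcript. Its 5' end overlaps the 3' end of LMNB2, which encodes lamin B2 on the same strand, over 257 nt (2427638 to 2427894), so strand does not separate reads there. The lowest of the 6 libraries was 0.712 of the highest. Every direction given below is that of libraries labelled with an siRNA, not of libraries shown to have lost TIMM13.

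The small TIM chaperones and the TIM22 insertion complex, in which TIMM13 works, had 8 tested members, of which 0 were called in the mean of both siRNAs and 5 had a positive fold change (median 0.14, camera adjusted p = 0.550, and adjusted p = 0.783 with an estimated correlation). TIMM8A, the partner that forms a complex with TIMM13, stood at 2.64 ± 0.187 in control, 7.82 ± 3.30 in siRNA 1 and 5.78 ± 1.34 in siRNA 2 (SD, n = 2, limma adjusted p = 0.129 for the mean of both). TIMM10B stood at 9.15 ± 0.362, 16.8 ± 0.487 and 14.9 ± 3.48 (adjusted p = 0.121). TIMM9 stood at 18.8 ± 0.101, 20.7 ± 0.958 and 8.88 ± 3.79 (adjusted p = 0.373). The 13 mRNAs encoded by mitochondrial DNA were all listed at 0 in all 6 libraries and could not be compared.

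**Figure D2:**
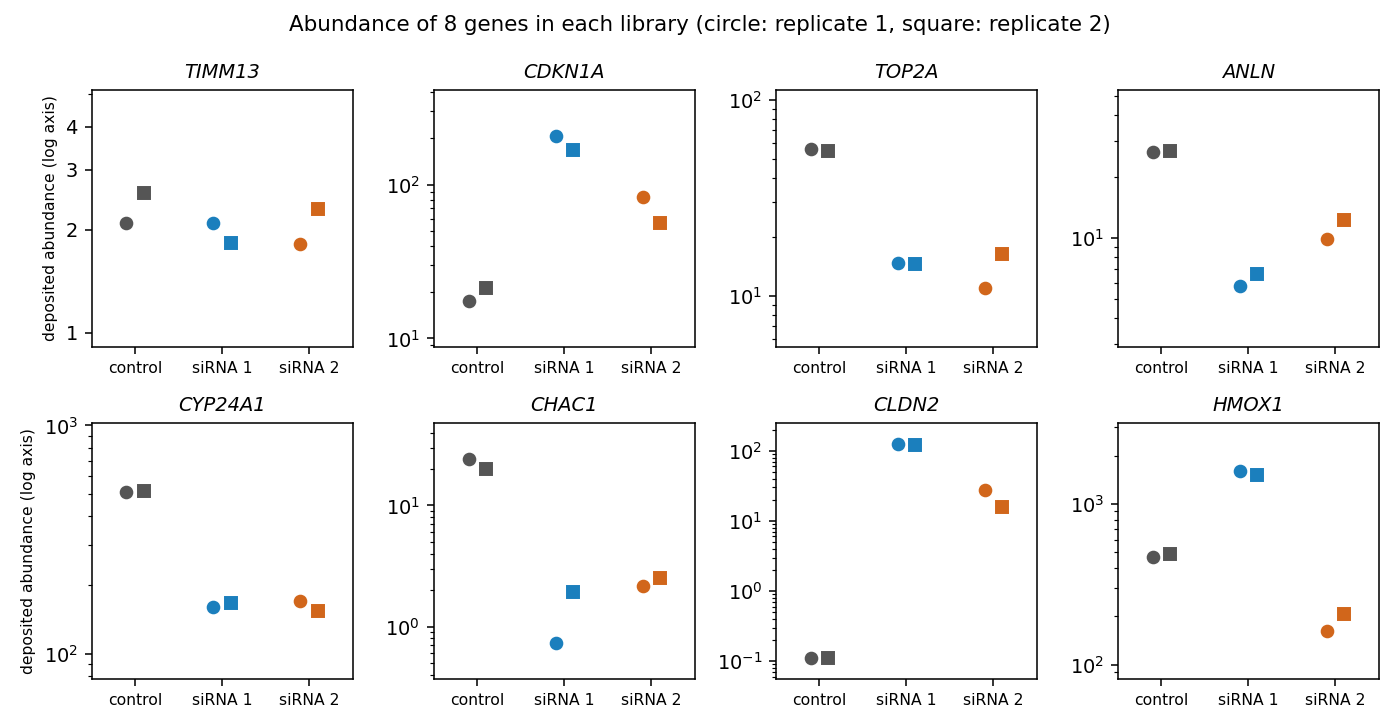
Each panel plots the deposited abundance of 1 gene (log y axis) in the 6 libraries by group (x axis), with circles for replicate 1 and squares for replicate 2. TIMM13 stays between 1.82 and 2.56 in all 6 libraries, while CYP24A1 lies at 509 and 515 in control and at 155 to 171 in the 4 siRNA libraries.

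In the libraries labelled siRNA 1, CDKN1A, which encodes the cell cycle inhibitor p21, rose from 19.4 ± 2.53 to 186 ± 27.8 (SD, n = 2, log2 fold change 3.20, SE 0.271, limma adjusted p = 0.0375). Of 55 tested genes of G2/M and mitosis 3 were called lower (adjusted p = 0.602 for the list with an estimated correlation). ANLN, an actin-binding protein of the cleavage furrow, went from 26.5 ± 0.252 to 6.22 ± 0.607. TOP2A, which untangles DNA before chromosomes separate, went from 55.2 ± 1.03 to 14.7 ± 0.104, and CDC25B, a phosphatase that starts mitosis, from 94.0 ± 0.478 to 37.5 ± 0.964. Their limma adjusted p were 0.0395, 0.0460 and 0.0427. CHAC1, a glutathione-degrading enzyme of the integrated stress response, fell from 22.1 ± 2.88 to 1.33 ± 0.846 and the cystine transporter SLC7A11 from 92.6 ± 4.44 by a log2 fold change of −2.22 (adjusted p = 0.0383 and 0.0434).

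Of the G2/M genes, 47 of 55 had a negative fold change with siRNA 1, with a median of −0.54. Of these genes, 3 were called lower and 0 higher, and 5 were lower adjusted over the list alone (camera adjusted p = 2.08e-07, and adjusted p = 0.602 with an estimated correlation). NF-kB targets and inflammatory cytokines had a median of −0.90 over 18 genes (camera adjusted p = 3.66e-05, and adjusted p = 0.333 with an estimated correlation). The chemokine CCL20, the NF-kB inhibitor TNFAIP3 and the chemokine CCL2 (chosen after its values were seen) were called lower, and 8 members were lower adjusted over the list alone. CCL20 went from 4.57 ± 0.331 to 0.706 ± 0.0969 and TNFAIP3 from 6.23 ± 0.556 to 0.970 ± 0.0379 (SD, n = 2). Integrated stress response genes had a median of −0.27 over 34 genes, with 2 called lower and 5 adjusted over the list alone (camera adjusted p = 0.00140, and adjusted p = 0.457 with an estimated correlation). Interferon response genes had a median of −0.39 over 20 genes, with 0 called and 2 lower adjusted over the list alone (camera adjusted p = 0.00438, and adjusted p = 0.457 with an estimated correlation). DNA replication genes had a median of −0.19 over 48 genes, and 1, the DNA methylation cofactor UHRF1, was called lower, or 2 adjusted over the list alone (camera adjusted p = 0.0266, and adjusted p = 0.579 with an estimated correlation).

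HMOX1, the haem-degrading oxygenase, rose with siRNA 1 from 476 ± 16.7 to 1561 ± 66.2 and ME1, the cytosolic malic enzyme, from 30.8 ± 0.433 to 85.8 ± 5.06 (SD, n = 2, limma adjusted p = 0.0427 and 0.0422). The lysosomal protease CTSB rose from 10.4 ± 1.06 to 89.0 ± 0.736, while the lysosomal protease CTSD fell to 4.76 and 0.176 from 221 and 209 in the control libraries (adjusted p = 0.0392 and 0.0490). BMF, a pro-apoptotic BH3 protein, fell from 5.75 ± 0.111 to 0.897 ± 0.0498 (adjusted p = 0.0422). In all, limma called 187 of 11486 genes with siRNA 1 (81 higher and 106 lower), 177 of them by 2-fold or more. The split was 18 higher and 13 lower with upper-quartile scaling, and 14 and 12 with equal totals. Limma called 0 genes without control replicate 1, control replicate 2, siRNA 1 replicate 1 or siRNA 1 replicate 2 (1334, 1285, 1291 and 1363 at an unadjusted p under 0.05), and 2350 (1247 higher and 1103 lower) and 2374 (1254 and 1120) without siRNA 2 replicate 1 and replicate 2. Library weights gave 1585 higher and 1416 lower, and a fit of only the groups compared 1260 and 1126. The run on genes with 1 transcript, which tested only 665 genes, gave 24 and 25.

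In the libraries labelled siRNA 2, TOP2A again fell, to 13.7 ± 3.80 (SD, n = 2, limma adjusted p = 0.0392). GDF15, a secreted stress cytokine, fell from 170 ± 35.0 to 40.8 ± 0.938, and CHAC1 to 2.36 ± 0.251 (adjusted p = 0.0394 and 0.0385). HMGA2, a chromatin architecture protein of embryonic and tumour cells, fell from 24.8 ± 0.395 to 2.41 ± 1.16 and the adhesion molecule NRCAM from 75.6 ± 0.194 to 10.9 ± 0.308 (adjusted p = 0.0326 and 0.0146). HMOX1, in contrast to siRNA 1, fell to 184 ± 31.9 (adjusted p = 0.0475). TOMM22, a receptor of the outer-membrane import pore, rose from 6.84 ± 0.00783 to 29.7 ± 5.75 (adjusted p = 0.0385). CDKN1A stood at 69.6 ± 19.4 (log2 fold change 1.77, SE 0.271, adjusted p = 0.0515) and was not called.

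Genes of the cell surface and matrix went both ways with siRNA 2: the collagen-crosslinking enzyme LOXL2, the integrin ITGA2 and the gelatinase MMP2 were called lower and the basement membrane collagen COL4A1 higher. LOXL2 went from 73.0 ± 1.33 to 26.8 ± 2.63 and COL4A1 from 2.93 ± 0.279 to 8.81 ± 1.59 (SD, n = 2). In glucose metabolism the hexokinase HK1 fell from 33.8 ± 2.04 to 7.84 ± 1.37, while PFKFB4, which makes an activator of glycolysis, rose from 2.02 ± 0.0729 to 6.22 ± 0.609 (limma adjusted p = 0.0385 and 0.0397). The cytokine LIF fell to 18.9 ± 5.87 from 66.8 ± 2.57 (adjusted p = 0.0467). CALR, a chaperone of the endoplasmic reticulum, rose from 146 ± 3.18 to 392 ± 74.0 (adjusted p = 0.0491). ATP6V0D1, a subunit of the lysosomal proton pump, rose from 18.5 ± 0.900 to 47.1 ± 4.08 (adjusted p = 0.0397). The ribosomal protein gene RPL29 fell from 497 ± 6.14 to 122 and 73.1 (adjusted p = 0.0394).

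With siRNA 2, 8 gene lists were called. G2/M genes had a median of −0.33 over 55 genes, 1 called lower and 7 adjusted over the list alone (camera adjusted p = 0.000164, and adjusted p = 0.631 with an estimated correlation). Integrated stress response genes had a median of −0.02 and a mean of −0.26 over 34 genes, with CHAC1, GDF15 and the pseudokinase TRIB3 (chosen after its values were seen) called lower, and 9 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0344, and adjusted p = 0.631 with an estimated correlation). Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, had a median of −0.32 over 20 genes, with 2 called lower and 4 adjusted over the list alone (camera adjusted p = 0.00427, and adjusted p = 0.631 with an estimated correlation). The 5 lists called higher were the nuclear-encoded respiratory chain (median 0.93, 75 genes, 2 called and 2 adjusted over the list alone), the mitochondrial ribosome (0.56, 72 genes, 0 and 0), mitochondrial chaperones and proteases (0.81, 16 genes, 0 and 2), autophagy and lysosome (0.76, 31 genes, 2 and 3) and cytosolic ribosomal proteins (1.10, 72 genes, 0 called higher and 1 lower, the same adjusted over the list alone). Their camera adjusted p were 0.00427, 0.0211, 0.0191, 0.0211 and 0.0316, and their adjusted p with an estimated correlation were 0.693, 0.669, 0.669, 0.645 and 0.760.

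These 5 lists stood far higher in siRNA 2 replicate 2 than in replicate 1: against the control mean, the respiratory chain had a median of 1.89 in replicate 2 and 0.04 in replicate 1, cytosolic ribosomal proteins 2.12 and −0.17, and autophagy and lysosome genes 1.26 and 0.21. The mitochondrial ribosome had 0.75 and 0.23 and the mitochondrial chaperones 1.30 and 0.27. The G2/M list had −0.04 in replicate 2 and −0.64 in replicate 1, the integrated stress response list 0.11 and −0.39, and the histone list −0.59 and −0.17. With the spread taken from the control and siRNA 1 groups alone, camera called 5 lists with siRNA 2 without siRNA 2 replicate 2, 0 higher and 5 lower. Without siRNA 2 replicate 1 the G2/M list was not called (median −0.04, camera adjusted p = 0.136), and without control replicate 2 camera called 5 lists. Limma called 345 genes with siRNA 2 (143 higher and 202 lower), 332 of them by 2-fold or more. A fit of only the groups compared called 0 (2111 at an unadjusted p under 0.05). Limma called 0 in the fit of all groups without control replicate 1, control replicate 2, siRNA 1 replicate 1 or siRNA 1 replicate 2 (1624, 1558, 2100 and 2105 at an unadjusted p under 0.05), and 4663 (2736 higher and 1927 lower) and 1763 (801 and 962) without siRNA 2 replicate 1 and replicate 2. Library weights gave 7 higher and 4 lower, and the run on only the 665 genes with 1 transcript 27 and 94.

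**Figure D3:**
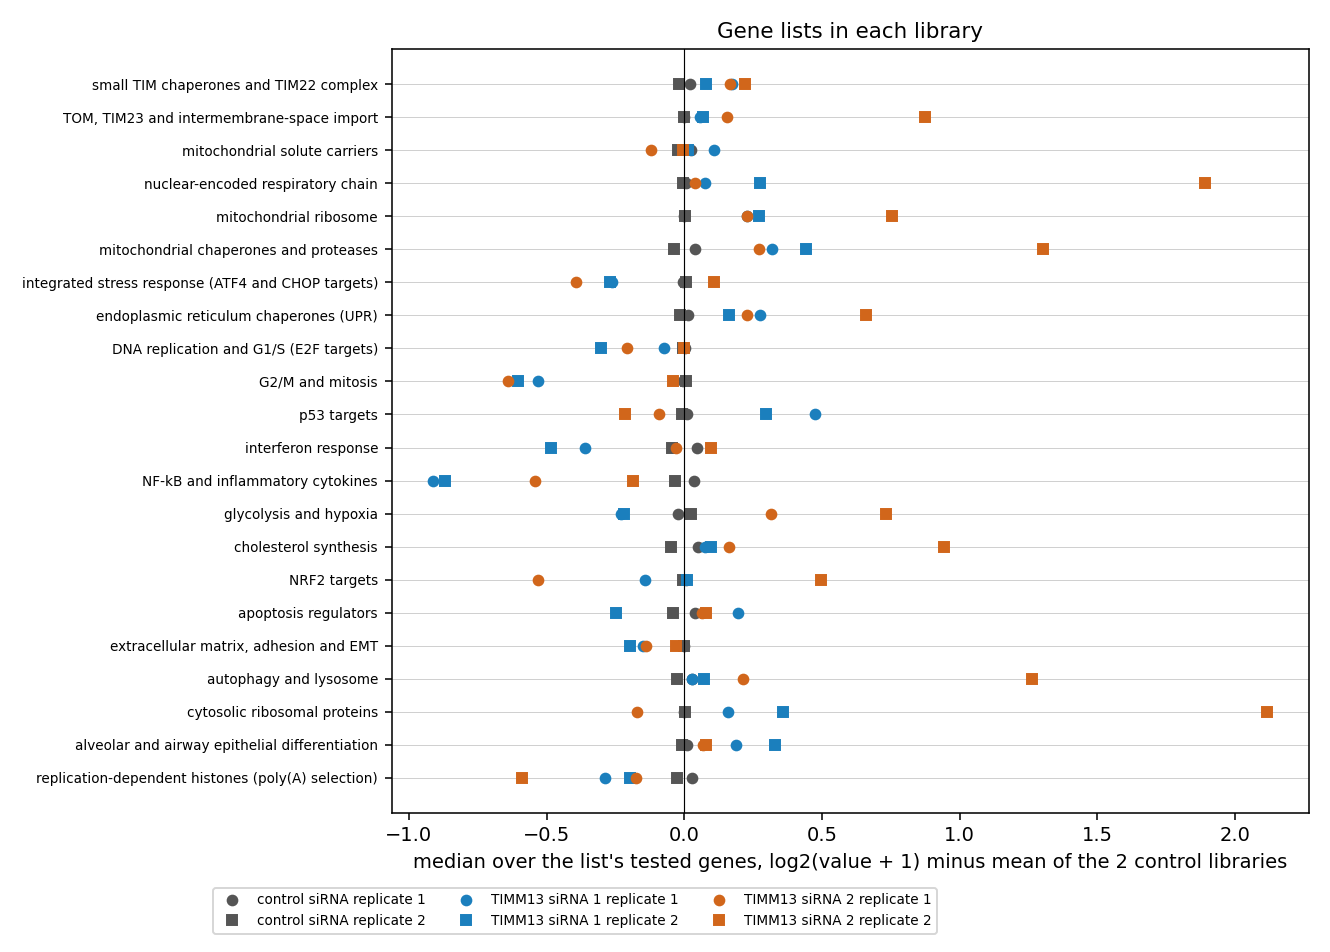
Each line of symbols is a gene list, and each symbol is the median over its tested genes of log2(value + 1) in 1 library minus the mean of the 2 control libraries (x axis, log2 units). The G2/M list lies at −0.53 and −0.60 in the siRNA 1 libraries, at −0.64 in siRNA 2 replicate 1 and at −0.04 in siRNA 2 replicate 2, which also holds the respiratory chain at 1.89 and the ribosomal proteins at 2.12.

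CYP24A1, the vitamin D catabolic hydroxylase, fell with both siRNAs, from 512 ± 3.84 in control to 164 ± 4.22 with siRNA 1 and 163 ± 11.5 with siRNA 2 (SD, n = 2, log2 fold changes −1.64 and −1.65, SE 0.161 each, limma adjusted p = 0.0402 and 0.0348). CLDN2, a tight junction protein, rose from 0.111 ± 0.00182 to 123 ± 4.24 and 21.8 ± 8.60. NRIP1, a nuclear receptor corepressor, stood at 0.0520 and 0.00673 in the control libraries, at 41.1 and 41.9 with siRNA 1 and at 22.8 and 13.6 with siRNA 2. MICB and ULBP1, surface ligands of the NK cell receptor NKG2D, fell from 18.7 ± 0.729 to 3.31 ± 0.472 and 2.01 ± 0.361, and from 5.96 ± 0.196 to 0.650 ± 0.284 and 0.475 ± 0.191. KIF18B, a kinesin of the mitotic spindle, fell from 15.9 ± 0.786 to 4.84 ± 0.291 and 3.12 ± 0.643, beside TOP2A, CHAC1 and CCL20 (given above for siRNA 1).

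Among the other large falls, SEC62, a component of the endoplasmic reticulum translocation machinery, went from 36.6 ± 0.356 to 0.311 ± 0.120 and 6.67 ± 0.642 (SD, n = 2). ID2, an inhibitor of DNA-binding differentiation factors, fell from 58.5 ± 0.706 to 11.4 ± 1.87 and 14.6 ± 3.97. NEIL3, a DNA glycosylase, fell from 14.4 and 15.7 to 3.46 ± 0.566 and 2.30 ± 0.576. PLSCR4, of the phospholipid scramblase family, fell from 25.5 ± 0.805 to 5.75 ± 1.23 and 4.35 ± 0.826. The readthrough RBM14-RBM4, whose signal is uncertain because it shares exons with its parent genes, stood at 54.1 and 35.0 in control, was listed at 0 in 3 siRNA libraries and stood at 1.18 in siRNA 2 replicate 2. Among the rises, NET1, a guanine nucleotide exchange factor, went from 3.39 ± 0.640 to 64.0 ± 6.22 and 43.5 ± 6.20. HCCS, which attaches haem to cytochrome c, rose from 1.68 ± 0.332 to 26.5 ± 1.85 and 22.5 ± 2.77. PSMD11, a proteasome subunit, went from 2.92 ± 0.401 to 34.0 ± 2.21 and 36.9 ± 18.1. MAEA, a subunit of a ubiquitin ligase, went from 1.99 ± 0.358 to 24.2 ± 1.28 and 19.7 ± 2.22. TCEAL9, of a family of transcription elongation factor-like proteins, went from 2.84 ± 0.672 to 46.7 ± 0.848 and 76.0 ± 11.3. APH1B, a gamma-secretase subunit, rose from 0.504 ± 0.104 to 19.5 ± 0.281 with siRNA 1 and to 13.7 and 12.3 with siRNA 2. The lipid flippase ATP9A rose from 0.256 ± 0.0640 to 11.2 ± 0.0795 and 9.65 ± 2.40. The zinc-finger protein THAP12 rose from 0.330 ± 0.0638 to 40.2 ± 1.19 and 15.7 ± 5.52. The hydrolase family member OVCA2 rose from 2.91 ± 0.990 to 27.4 ± 4.80 and 41.7 ± 13.2. ARHGEF10, of the same class as NET1, was listed at 0 in both control libraries and stood at 8.43 and 7.44 with siRNA 1 and at 10.9 and 11.7 with siRNA 2. Of the 24 genes with the largest shared changes, 2 had 1 annotated transcript, as did 5 of all 69 genes called the same way. The others of the 24 could have changed transcript and not level.

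In all, 69 genes were called the same way with both siRNAs, 42 higher and 27 lower, and 1, HMOX1, in opposite directions. Independent lists of these sizes would share 1.01 higher and 1.86 lower genes, but both comparisons used the same 2 control libraries, which cannot be split, so how much of the overlap comes from them is unknown. Simulations with no effect gave 0 shared genes, but the test called only 0.0337% and 0.0341% of unchanged genes in simulated data, so that 0 does not measure the part of the controls. Across genes the fold changes of both siRNAs correlated at 0.467, against 0.50 in the simulations, and 65.3% of genes had the same sign, against 66.7%. Their covariance was 0.288, against a simulated 0.187, a difference of 0.101. The simulations gave each gene the same spread in all 6 libraries. In the data the median replicate SD was 0.0864 in control, 0.102 in siRNA 1 and 0.320 in siRNA 2. The simulated correlation, sign share and covariance therefore do not show what shared controls alone would give here, and no conclusion is drawn from them. Genes called the same way numbered 16 higher and 6 lower with upper-quartile scaling, and 3 and 3 with equal totals. With a pseudocount of 0.1 they numbered 41 higher and 9 lower, and with a pseudocount of 5 38 and 31. The filter at 5 gave 44 and 16. The number of shared falls thus depended on the constant added and on the filter. A run on only the 665 genes with 1 transcript gave 8 and 13. It tested 5 of the 69 genes and called these 5 again, so its other shared genes are not among the 69. A fit of only the groups compared gave 0 shared genes (4395 with siRNA 1 and 2111 with siRNA 2 at an unadjusted p under 0.05). Limma called 0 genes with both siRNAs without control replicate 1, control replicate 2, siRNA 1 replicate 1 or siRNA 1 replicate 2, for which the counts at an unadjusted p under 0.05 are those given with each siRNA (1334 and 1624 without control replicate 1). Without siRNA 2 replicate 1, or without siRNA 2 replicate 2, it called genes in the same direction with both siRNAs and other genes in opposite directions. Genes called in opposite directions numbered 0 with upper-quartile scaling, 0 with equal totals and 2 with a pseudocount of 5. They numbered 2 with the filter at 5 and 2 with library weights, so HMOX1 as the only such gene holds for the main fit.

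**Figure D4:**
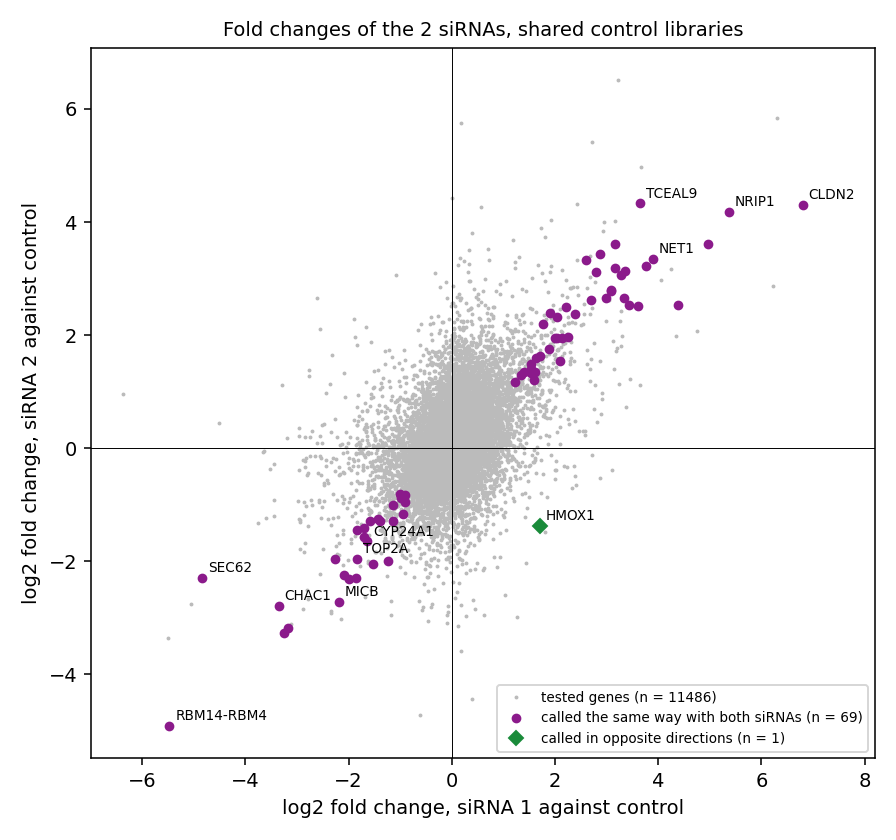
Each point is 1 of 11486 tested genes, with its log2 fold change of siRNA 1 against control on the x axis and of siRNA 2 against the same control on the y axis. The 69 genes called the same way lie in the upper right (42) and lower left (27), and HMOX1 is the gene called in opposite directions.

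For the mean of both siRNAs, G2/M genes had a negative fold change in 46 of 55 members, with a median of −0.49. TOP2A and ANLN were called lower, and 13 members were lower adjusted over the list alone (camera adjusted p = 1.81e-07, and adjusted p = 0.538 with an estimated correlation). KIF14, a kinesin of cytokinesis, stood at 8.12 ± 0.0733 in control, 3.85 ± 0.124 with siRNA 1 and 3.80 ± 0.137 with siRNA 2 (SD, n = 2, limma adjusted p = 0.0568). NF-kB targets had a median of −0.56 with CCL20 and TNFAIP3 called lower, and 7 adjusted over the list alone (camera adjusted p = 0.00176, and adjusted p = 0.538 with an estimated correlation). With siRNA 2 alone that list had a median of −0.17 and was not called (camera adjusted p = 0.0913). Against the control mean it stood at −0.91 and −0.87 in the siRNA 1 libraries and at −0.54 and −0.19 in the siRNA 2 libraries. Integrated stress response genes had a median of −0.39 with CHAC1 called lower, and 6 adjusted over the list alone (camera adjusted p = 0.00192, and adjusted p = 0.538 with an estimated correlation). MTHFD2, a mitochondrial folate enzyme, stood at 62.3 ± 1.63, 27.8 ± 4.79 and 29.6 ± 2.07 (adjusted p = 0.0580). DNA replication genes had a median of −0.16 over 48 genes with UHRF1 called lower, and 5 adjusted over the list alone, and histone genes −0.17 with 0 called and 4 adjusted over the list alone. Their camera adjusted p were 0.0174 and 0.0204, and their adjusted p with an estimated correlation were 0.538 and 0.538. Against the control mean the DNA replication list stood at −0.07 and −0.30 in siRNA 1 replicates 1 and 2. In siRNA 2 replicates 1 and 2 it stood at −0.21 and −0.002, and it was not called for siRNA 2 alone (camera adjusted p = 0.0740). With fry only the NF-kB list was called. Apart from fry and the estimated correlation, which lost both calls, the histone call was lost in 3 of 15 alternatives (medians −0.436 to −0.0561, highest camera adjusted p = 0.633) and the DNA replication call in 1 of 15 (highest 0.148).

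The lists called higher for the mean of both siRNAs were the respiratory chain, the mitochondrial ribosome and the mitochondrial chaperones and proteases, with medians of 0.51, 0.36 and 0.57. Their camera adjusted p were 0.0103, 0.0103 and 0.0174, and their adjusted p with an estimated correlation were 0.783, 0.783 and 0.783. All 3 calls were also lost with fry (adjusted p = 0.323, 0.227 and 0.227), and in 2, 1 and 1 of the 15 other alternatives (highest camera adjusted p = 0.332, 0.064 and 0.171). UQCRB, a subunit of complex III, rose from 9.70 ± 1.28 to 54.4 ± 2.43 and 54.1 ± 2.20, and COX7B, of complex IV, from 11.8 ± 0.801 to 53.3 ± 4.90 and 36.3 ± 4.49 (SD, n = 2, limma adjusted p = 0.0211 and 0.0388); they were the 2 members called, also adjusted over the list alone. Of the mitochondrial ribosome 0 were called by either count, and of the chaperones 0, or 2 adjusted over the list alone. The chaperonin HSPD1 stood at 73.5 ± 41.2, 305 ± 14.8 and 249 ± 68.9 and the protease LONP1 at 5.53 ± 0.377, 15.7 ± 1.43 and 23.9 ± 11.6 (adjusted p = 0.0876 and 0.0839). Without siRNA 2 replicate 2, camera called 4 lists, 0 higher and 4 lower, and the respiratory chain had a median of 0.10 (camera adjusted p = 0.332). Limma called 137 genes, 83 higher and 54 lower, 131 of them by 2-fold or more. It called 0 without control replicate 1, control replicate 2, siRNA 1 replicate 1 or siRNA 1 replicate 2 (1329, 1260, 1739 and 1765 at an unadjusted p under 0.05), and 4066 (2376 higher and 1690 lower) and 2319 (1120 and 1199) without siRNA 2 replicate 1 and replicate 2. Library weights gave 350 higher and 441 lower, the run on only the 665 genes with 1 transcript 21 and 47, and a fit with both siRNAs as 1 group 24 and 9.

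CDKN1A was the 1 p53 target called for the mean of both siRNAs, with a log2 fold change of 2.48 (SE 0.234, limma adjusted p = 0.0388). PPM1D, a phosphatase that p53 induces, stood at 10.4 ± 1.01 in control, 4.87 ± 0.272 with siRNA 1 and 4.22 ± 0.910 with siRNA 2 (SD, n = 2, adjusted p = 0.0671). Beside the small TIM list, 13 lists were not called. Their medians were 0.25 for TOM, TIM23 and intermembrane-space import, 0.02 for mitochondrial solute carriers, 0.39 for endoplasmic reticulum chaperones, 0.12 for p53 targets, −0.20 for the interferon response, −0.04 for glycolysis and hypoxia and 0.24 for cholesterol synthesis (camera adjusted p = 0.497, 0.550, 0.550, 0.741, 0.0824, 0.967 and 0.550). They were 0.08 for NRF2 targets, 0.06 for apoptosis regulators, −0.18 for extracellular matrix, adhesion and EMT, 0.33 for autophagy and lysosome, 0.67 for cytosolic ribosomal proteins and 0.21 for alveolar and airway differentiation (camera adjusted p = 0.497, 0.617, 0.169, 0.136, 0.0688 and 0.528). The lowest adjusted p of any list with an estimated correlation was 0.538. For the solute carriers, the NRF2 targets and the apoptosis regulators camera's direction was down while the median was above 0. Of the markers of other cell types, COL1A1, ACTA2 and CD14 were tested and none was called for the mean of both. The collagen COL1A1 stood at 0.776 ± 0.0267 in control, 2.08 ± 0.344 with siRNA 1 and 3.41 ± 1.17 with siRNA 2 (SD, n = 2, limma adjusted p = 0.0809 for the mean of both). ACTA2, smooth muscle actin, stood at 1.91 ± 0.517, 14.1 ± 0.308 and 1.15 ± 0.927, and the monocyte receptor CD14 at 4.28 ± 0.264, 2.05 ± 0.351 and 6.72 ± 0.383.

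Compared with each other, the siRNAs differed in HMOX1, which was 3.09 log2 units higher with siRNA 1 than with siRNA 2 (SE 0.197, limma adjusted p = 0.0191), and in HMGA2 and NRCAM, 3.23 and 3.10 higher (adjusted p = 0.0304 and 0.0157). The F-box proteins FBXW10 and FBXW10B, related genes between which reads may be split, were 3.62 and 4.26 log2 units higher with siRNA 1 (adjusted p = 0.0160 and 0.0157). Lower with siRNA 1 were DPY19L1, a C-mannosyltransferase, at 0.993 ± 0.0693 against 61.9 ± 6.35, the RNA helicase DDX17 at 5.70 ± 1.18 against 80.7 ± 19.5, and CTSD at 4.76 and 0.176 against 413 and 423. The carbonyl reductase CBR1 was listed at 0 and 0.648 with siRNA 1 and at 51.0 and 71.1 with siRNA 2. ABCF2, of the ABC protein family, was listed at 0 in both siRNA 1 libraries and at 17.4 and 24.0 with siRNA 2. Its readthrough ABCF2-H2BK1, with shared exons and so uncertain, stood at 9.44 and 8.34 with siRNA 1 and was listed at 0 in both siRNA 2 libraries.

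In this comparison camera called p53 targets higher with siRNA 1 (median 0.30, 29 genes, camera adjusted p = 0.0146, and adjusted p = 0.535 with an estimated correlation), with 4 called higher and 7 adjusted over the list alone. Interferon response genes were called lower (median −0.65, 20 genes, camera adjusted p = 0.0382, and adjusted p = 0.535 with an estimated correlation), with 1 called lower, and 4 lower and 1 higher adjusted over the list alone. Genes of glycolysis and hypoxia were also called lower (median −0.73, 29 genes, camera adjusted p = 0.0146, and adjusted p = 0.535 with an estimated correlation), with 3 called lower, and 4 lower and 2 higher adjusted over the list alone. The histone list had a median of 0.39 over 20 genes (camera adjusted p = 0.0386, and adjusted p = 0.583 with an estimated correlation), with 0 called and 2 higher adjusted over the list alone. This rested on siRNA 2 replicate 2 at −0.59 against the control mean, as siRNA 2 replicate 1 at −0.17 lay above both siRNA 1 libraries at −0.29 and −0.20. Limma called 376 genes, 219 higher and 157 lower with siRNA 1, and 351 of them by 2-fold or more. A fit of only the groups compared called 0 (1997 at an unadjusted p under 0.05). Limma called 0 in the fit of all groups without control replicate 1, control replicate 2, siRNA 1 replicate 1 or siRNA 1 replicate 2 (1998, 1995, 1517 and 1556 at an unadjusted p under 0.05), and 4581 (1951 higher and 2630 lower) and 1647 (962 and 685) without siRNA 2 replicate 1 and replicate 2. Library weights gave 2 higher and 3 lower, and the run on only the 665 genes with 1 transcript 54 and 17.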

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

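The tests of TIMM13 and the count of genes seen in 1 library were chosen only after the result was seen, and those of transcript length and of 1 transcript per gene were written before their values were computed.

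Both siRNAs target TIMM13, so values that differ between them are given here as siRNA 1 minus siRNA 2 in log2 units. Higher with siRNA 1 were CLDN2 (2.497), MMP2 (0.97), RPL29 (2.52), ACTA2 (2.88), FBXW10B (4.26), FBXW10 (3.62), HMGA2 (3.23), NRCAM (3.10) and HMOX1 (3.09). Lower with siRNA 1 were SEC62 (−2.55), CTSD (−7.33), CD14 (−1.34), DPY19L1 (−4.98) and DDX17 (−3.60). Genes with a library listed at 0 are given by library. ABCF2 was listed at 0 in both siRNA 1 libraries and at 17.4 and 24.0 with siRNA 2, and CBR1 at 0 and 0.648 against 51.0 and 71.1. ABCF2-H2BK1 stood at 9.44 and 8.34 with siRNA 1 and was listed at 0 in both siRNA 2 libraries. Among lists, the medians were 0.30 for p53 targets, −0.65 for the interferon response, −0.73 for glycolysis and hypoxia and 0.39 for replication-dependent histones, the last from siRNA 2 replicate 2 alone (−0.59 against the control mean, with −0.17 in replicate 1 and −0.29 and −0.20 with siRNA 1). The cause was not tested for any of these.

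TIMM13 stood at 2.32 ± 0.332 in control and at 1.96 ± 0.183 and 2.06 ± 0.344 in the siRNA groups (SD, n = 2). A swap of labels between control and siRNA libraries would leave some libraries far below others only if TIMM13 fell and this row shows the fall. The lowest library was 0.712 of the highest. This speaks only against a swap of libraries in which the row fell, and otherwise cannot tell swapped labels from right ones. The table could hold a minor transcript of the gene: 0 of 8 other tested members of its list had a lower mean (TIMM13 2.12, the others 5.41 to 26.8), which this explanation allows. It was written after the values were seen, and a knockdown that had ended by harvest would look the same.

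The library labelled siRNA 2 replicate 2 held cytosolic ribosomal protein and respiratory chain genes a median of 1.98 log2 units above siRNA 2 replicate 1 over 147 members. A transcript length trend may add to this but left 1.39 (bootstrap SE 0.0897) after it was taken out. If the table held 1 transcript per gene, genes with few transcripts should be spared: the ratio of the difference at 1 to 3 transcripts (14 members) to that at 6 or more (109 members) was 0.30 (SE 0.246), too few members to decide. In this library 37 genes stood at 10 or more while under 1 in the other 5, 12.3 times the highest number in any other library, which is what values made from other transcripts could give. Genes under 1 in this library and at 10 or more in the other 5 numbered 11, against 12 to 16 for the other libraries. The excess thus lay only in gained genes, and the count does not decide the question. A different state of the cells behind that library was not tested.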

How the results depend on the processing

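The alternatives with 1 annotated transcript, library weights and genes within 2-fold between replicates were chosen only after the result was seen and added after the data were seen. The counts of called genes depended on the libraries and settings used. The main fit gave each gene 1 spread for all 3 groups, with a median residual SD of 0.249 log2 units. That lies above the median replicate SD of control (0.0864) and siRNA 1 (0.102) and below that of siRNA 2 (0.320). Both siRNAs thus have the same SE, although the siRNA 2 replicates differed more. The fit of only the groups compared, given below, takes the spread from those groups alone. It called more genes than the main fit with siRNA 1 and 0 with siRNA 2. It also changes the residual degrees of freedom, so how far the shared spread accounts for each count is not known. In order, the counts are for siRNA 1, siRNA 2, the mean of both, siRNA 1 against siRNA 2, and both siRNAs the same way. Upper-quartile scaling gave 31, 112, 36, 76 and 22, and equal totals 26, 19, 36, 34 and 6. A fit of only the groups compared gave 2386, 0, 33 (both siRNAs as 1 group of 4), 0 and 0. With the replicate number as a block limma called 0, 0, 0, 0 and 0 (2008, 2556, 2287 and 2436 at an unadjusted p under 0.05 in the first 4). The run on genes with 1 transcript tested only 665 genes and gave 49, 121, 68, 71 and 21. As shares of the genes tested, these were all higher than in the main fit, so the lower counts do not mean fewer calls per gene. Library weights gave 3001, 11, 791, 5 and 6. No filter gave 110, 43, 239 and 33 in the last 4. Leaving out 1 library gave 0 to 2374, 0 to 4663, 0 to 4066, 0 to 4581 and 0 to 1157. It was 0 without any 1 of the control or siRNA 1 libraries. For lists, siRNA 1, siRNA 2 and the mean of both had 0, 0 and 0 with an estimated correlation and 2, 0 and 1 with fry. The filter at 5 gave 3 for siRNA 1, and genes within 2-fold between replicates 5 for siRNA 2. Leaving out 1 library gave 5 to 7, 5 to 9 and 4 to 9 lists, with 5 for siRNA 2 without control replicate 2 or siRNA 2 replicate 2, and 4 for the mean without siRNA 2 replicate 2. In the mean of both, some lists that were not called changed direction in the set test. Glycolysis and hypoxia had a median of −0.0443 with fry, −0.0443 with cameraPR, −0.12 with median of ratios and 0.19 for genes within 2-fold between replicates. It ranged from −0.0635 to 0.19 when 1 library was left out, p53 targets from 0.0660 to 0.18, and NRF2 targets from −0.23 to 0.22. Cytosolic ribosomal proteins had −0.0933 for genes within 2-fold between replicates. The planned count-based tests were not run because the values are not counts.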

Other observations

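The ligand and ferritin genes and the tests of the control libraries were chosen only after the result was seen, while the tests of G2/M genes and of readthrough genes were written before their values were computed.

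Beside MICB and ULBP1, 3 other ligand genes of the NK cell receptor NKG2D were looked at singly. MICA stood at 4.65 and 8.36 in control, 2.31 and 5.90 with siRNA 1 and 4.31 and 13.8 with siRNA 2 (limma adjusted p = 0.686 and 0.805 with siRNA 1 and siRNA 2). ULBP3 stood at 3.35 ± 0.629, 2.15 ± 0.125 and 1.12 ± 0.413 (SD, n = 2, adjusted p = 0.313 and 0.0732), so neither gene was called. RAET1G rose with siRNA 2 from 1.97 ± 0.0817 to 9.69 ± 2.15 (limma adjusted p = 0.0389).

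The ferritin light chain FTL fell with siRNA 2, from 5288 ± 237 in control to 1455 ± 228 (SD, n = 2, limma adjusted p = 0.0376), as HMOX1, which releases iron from haem, did. With siRNA 1, where HMOX1 rose, FTL stood at 5648 ± 228. The heavy chain FTH1 stood at 2396 ± 34.2, 2642 ± 22.0 and 1096 ± 179, with a log2 difference of 1.28 between siRNA 1 and siRNA 2 (adjusted p = 0.0487).

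The G2/M list had a median of −0.49 in the mean of both siRNAs, but an adjusted p of 0.538 with an estimated correlation of 0.278 between its genes. Its median was −0.64 in siRNA 2 replicate 1 and −0.04 in replicate 2, and without replicate 1 the list was not called for siRNA 2 (camera adjusted p = 0.136). Chance jumps of single genes with several transcripts could lower a list, yet 0% of 10000 random lists matched on level and transcript number were as low, the lowest at −0.25. Random lists treat genes as independent, so this speaks only against separate jumps and leaves open variation between libraries that the G2/M genes share. No biological explanation was tested.

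The table may hold values of 1 transcript per gene, or split the signal of a gene between transcripts unevenly. Between the 2 control libraries, the share of genes over 2-fold apart was 4.62 times as high for genes with 6 or more transcripts as for genes with 1, matched on level (bootstrap 2.72 to 10.7), which uneven splitting of any kind would also give. Sampling noise of low values would put the jumps among low genes, but in ratios of the values with no constant added the share at a mean of 50 or more was 1.47 times that at 1 to 5 (SE 0.185; 9.86% of 771 genes against 6.71% of 3847). Fold changes of readthrough genes ran against those of their parents (rho −0.322, permutation p = 0.0195). They would do so if the signal of a locus fell to either. The 53 pairs came from 36 readthrough rows and are not independent, so this p may be too small. Pairs were found by hyphenated name, which also took in KBTBD11-OT1, an overlapping transcript. Single genes with many transcripts could thus have changed transcript and not level, which these tests do not decide.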
